A study of Mus musculus with 8 samples.

How the data were processed

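RNA from the orbital frontal cortex of C57BL/6 mice aged 12 weeks was sequenced in 8 libraries, made with a stranded kit from total RNA, per the labels' protocols. The labels put 4 libraries in a knockdown group, treated with short hairpin RNA against circHomer1/Homer1b, and 4 in a control group treated with a scrambled hairpin. Nothing in the labels says that each library came from a separate animal, so the p-values measure the spread between these libraries.

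The authors deposited 1 table of genes and 1 table of transcripts, with values in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers. FastQC, cutadapt, HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build and the annotation are not given in the sources used here. Of 13130 genes, 87.5% had an Ensembl identifier and version found in GENCODE M21, and all 11493 of these had identical coordinates there, so coordinates are given on GRCm38. All rows of both tables were protein-coding, and the higher of the 2 group means was never under 0.50 FPKM, a filter read from the values. The transcript table held 24526 transcripts. In the 1194 genes with 1 annotated transcript, 100.0% of the deposited values were equal in both tables within a relative tolerance of 1e-06. The gene value was not in general the sum of the transcripts. Over all genes with listed transcripts, those 1194 included, the median ratio of the gene value to the sum of its listed transcripts was 0.858. Deposited FPKM values carry no read counts. Low values of 1-transcript genes, multiplied by transcript length, showed no common step: at most 28.7% were whole multiples of the lowest one within 0.1 of a step. The depth of each library is therefore unknown, and no interval or detection floor that needs counts is given.

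Values were taken to log2(FPKM + 1), so a fold on this scale understates the change of low genes. Genes or transcripts with a mean of at least 0.5 FPKM over the 8 libraries were tested, 13004 genes and 23415 transcripts. The test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend and robust settings, two-sided), knockdown against control, with no block. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Homer1 and its isoforms were also compared with an exact two-sided permutation test over the 70 labelings of 4 of 8 libraries, whose smallest possible p is 0.0286.

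A total of 32 gene lists (cell types, brain regions, synaptic and stress pathways) were fixed before the data were examined, with the tests, the alternatives and the rule for naming genes. The 31 lists with at least 5 measured members were tested with camera (limma) at a preset inter-gene correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Fry's p for a shift in 1 direction was used unless stated otherwise. The list of lymphocyte and leukocyte genes had 1 measured member and was not tested. A list's difference is the mean log2 difference of its members minus the mean over all tested genes, and its score in a library is the mean log2 deviation of its members from their means over the 8 libraries. Named genes were Homer1, Homer2 and Homer3; the genes past the threshold, or, since none was, the 10 with the smallest p in each direction among those with a mean of at least 1 FPKM, given as values; and for each list up to 4 members passing over the list alone, or otherwise up to 2 with the smallest p. Predicted genes were left out of the rule by p, and some genes that the rule takes are not reported here. Arc, Fos, Drd1, Drd2, Cdhr1, Doc2g, Slc17a7 and Gad1 fall outside the rule and were chosen after their values were seen.

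On simulated data with the real means and spread, the gene test found 44 of 50 genes changed 1.5-fold and 45 of 50 changed 2-fold among 13004, with 9 false calls. The transcript test found 13 of 50 transcripts changed 1.5-fold and 40 of 50 changed 4-fold among 23415, with 5 false calls. In each table, 50 rows at each of 1.5-, 2-, 3- and 4-fold were changed together, which eases the adjusted threshold. The folds were added on the log2(FPKM + 1) scale and are larger in FPKM for low rows. Simulated genes were also independent of each other, which the real ones are not. The rates do not apply where few rows change, so they do not exclude changes of these sizes in the real data.

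Alternatives covered the pseudocount, the filter on low values, rescaling, quantile normalization, the empirical Bayes settings, library weights, a replicate block, each library left out, and the list test. Others were chosen after seeing the data: removal of a GC content and length trend per library (available for 99.4% of genes), the sum of listed transcripts as the gene value, and a covariate for striatal marker level. No 2 libraries were identical (log2 correlations from 0.971 to 0.99). circHomer1 shares its exons with the linear transcripts and is not a row with its own identifier, so no circHomer1 value is given.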

Results

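The series compared the orbital frontal cortex, a prefrontal region involved in flexible reward-guided behaviour, between 4 libraries with a circHomer1/Homer1b knockdown and 4 scrambled-hairpin controls. Summed gene FPKM per library ran from 214316 to 224323, and the share of mitochondrially encoded genes from 12.2% to 14.5%. Read depth was not given.

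Homer1, the targeted gene, encodes postsynaptic scaffold proteins that bind group I metabotropic glutamate receptors (ENSMUSG00000007617, chromosome 13, 93299635 to 93405129, plus strand, GRCm38). Its level was 22.5 ± 3.13 FPKM in controls and 17.8 ± 1.49 FPKM in the knockdown group (SD, n = 4 each), a log2 difference of -0.31 ± 0.10 (SE). The control libraries read 23.5, 26.3, 21.3 and 18.9 FPKM, and the knockdown libraries 18.9, 16.5, 16.6 and 19.3 FPKM. All 4 knockdown libraries lay below the control mean, and the groups overlapped. The difference did not pass the threshold over all genes (limma, Benjamini-Hochberg adjusted p = 0.273), nor in the exact permutation test (p = 0.0857; 0.386 after Benjamini-Hochberg adjustment over 9 Homer1 values). The paralogs Homer2 (3.91 ± 0.377 against 5.18 ± 2.23 FPKM, control against knockdown) and Homer3 (1.33 ± 0.251 against 1.45 ± 0.286 FPKM) had limma adjusted p of 0.583 and 0.774 (SD, n = 4 each). The difference for Homer3 was smaller than the SD of either group. For Homer2 it was smaller than the SD of the knockdown group but larger than that of the controls. The difference for Homer2 was 0.27, and 0.05 without knockdown replicate 4, which read 8.32 FPKM against 3.41 to 5.20 FPKM in the other knockdown libraries, and 0.02 with the striatal score as a covariate. The direction for Homer3 flipped to -0.04 when a GC content and length trend was removed.

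**Figure D1:**
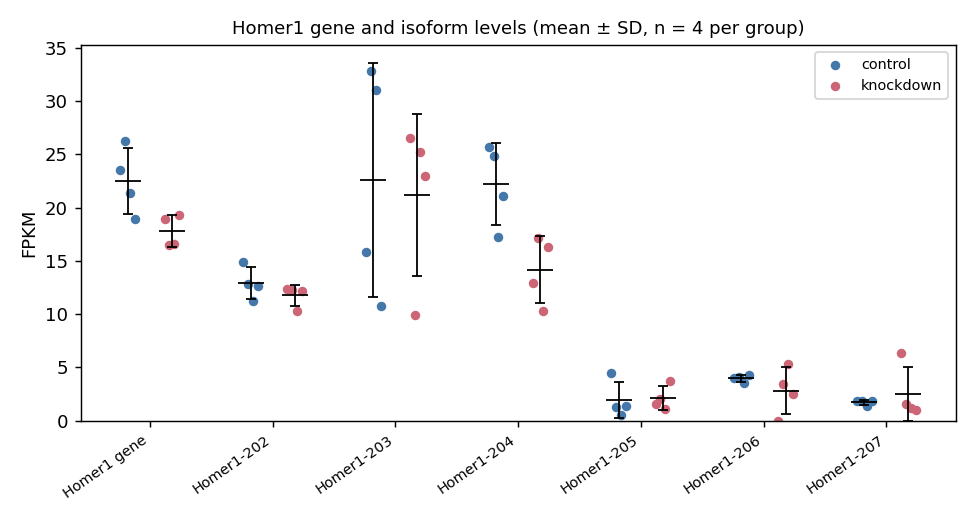
FPKM (y axis) of the Homer1 gene and its 6 listed isoforms (x axis), with 1 point per library, blue for control and red for knockdown, and black bars for the mean ± SD of 4 libraries. Homer1-204 was the isoform without overlap between the groups, 17.3 to 25.7 FPKM in controls and 10.3 to 17.2 FPKM in the knockdown libraries. The gene value is not the sum of the isoform values.

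Among isoforms, the short form Homer1-204 was the one without overlap between the groups, by 17.2 against 17.3 FPKM at the closest. Homer1-204 (chromosome 13, 93304495 to 93360462, 5 exons, 186 codons) ends in an extended exon 5 and encodes the activity-induced Homer1a protein, which lacks the coiled-coil tail. It read 22.2 ± 3.85 FPKM in controls and 14.2 ± 3.18 FPKM in the knockdown group (SD, n = 4 each), a log2 difference of -0.62 ± 0.18, and was below every control in all 4 knockdown libraries. The exact permutation p was 0.0286, the smallest these 70 labelings can give, and 0.257 after Benjamini-Hochberg adjustment over the 9 Homer1 values. Limma's adjusted p over all transcripts was 0.565. The long isoforms Homer1-202 (370 codons) and Homer1-203 (366 codons) read 12.9 ± 1.48 against 11.8 ± 1.00 FPKM and 22.6 ± 11.01 against 21.2 ± 7.64 FPKM, control against knockdown. Their sum differed by -0.09 on the log2 scale (exact permutation p = 0.714). All 6 listed isoforms summed to 65.4 ± 10.5 FPKM in controls and 54.6 ± 6.17 FPKM in the knockdown group. That log2 difference was -0.25 (exact permutation p = 0.171). The gene value lay far below this sum, so gene and isoform levels of Homer1 are not on the same scale. Homer1-203 ranged from 9.93 to 32.9 FPKM over the 8 libraries, so its spread was wider than any group difference, and its direction turned when single libraries were left out.

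The low isoforms Homer1-205, Homer1-206 and Homer1-207 had log2 differences of 0.18, -0.65 and 0.16 (limma adjusted p of 0.913, 0.74 and 0.923). Homer1-206 was listed at 0 in knockdown replicate 1 and at 3.42, 5.31 and 2.53 FPKM in the others. As a share of the summed Homer1 isoforms, Homer1-204 made up 34.4% ± 6.40 in controls and 26.4% ± 7.93 in the knockdown group (exact permutation p = 0.171). Homer1-201, whose 354 codons are the length of Homer1b, was not analysed here, and no listed transcript was tied to Homer1b. The labels do not say whether each knockdown library received a hairpin against circHomer1, Homer1b or both, so the Homer1 values are not a readout of a single target. All 6 listed isoforms carry the exon starts of exons 2 to 5 (chromosome 13, 93341756 to 93356079), the exons of circHomer1, so a fragment from the circle cannot be told from a linear one in these values.

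**Figure D2:**
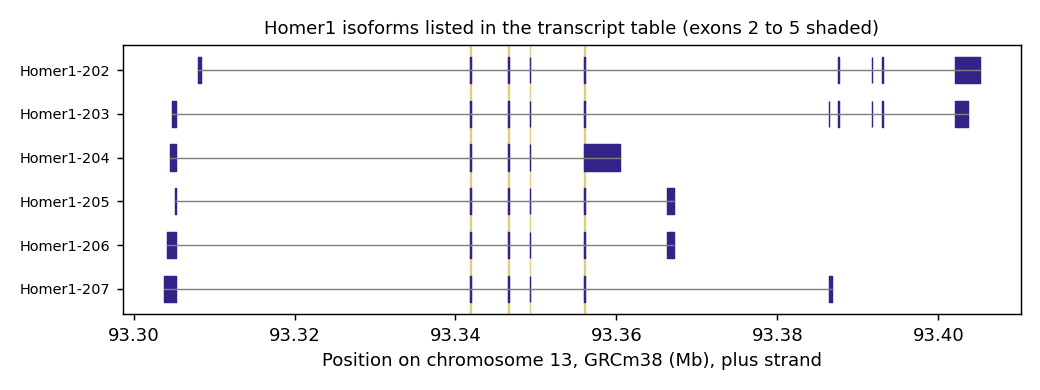
Exons (dark boxes) of the 6 listed Homer1 isoforms, 1 per line, against the position on chromosome 13 in megabases (x axis, GRCm38), with exons 2 to 5 shaded. Homer1-204 ends at 93360462 inside the extended exon 5, whereas Homer1-202 and Homer1-203 run on to 93405129 and 93403681.

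Across the transcriptome, no gene passed the threshold (limma with Benjamini-Hochberg adjustment, 13004 genes, smallest adjusted p 0.266). At an unadjusted p under 0.05 there were 1842 genes, 14.2% of those tested against 650 expected, with 1183 higher and 659 lower in the knockdown group. The split was 964 higher to 839 lower after median-of-ratios rescaling. Without control replicate 1 the count was 1199, and it was 1185 when a GC content and length trend was removed and 1046 with the striatal marker score as a covariate. The groups of 4 did not overlap in 9.15% of genes, where chance gives 2.86%.

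The genes with the smallest p are given as values. Hopx, a small homeodomain protein, read 13.6 ± 1.11 against 24.6 ± 4.64 FPKM (SD, n = 4, control against knockdown), a log2 difference of 0.79 ± 0.12. Pnck, a calcium/calmodulin-dependent kinase, read 15.0 ± 1.29 against 23.6 ± 3.39 FPKM, and Vps37d, a subunit of the endosomal sorting machinery, 7.43 ± 0.765 against 10.6 ± 0.708 FPKM. Dennd6b, Smim27, Hdac7, Hook2, Ccdc74a, Sergef and Lrrc73 had log2 differences from 0.29 to 0.38, and each was above every control in all 4 knockdown libraries. With the summed transcripts as the gene value, the direction for Hdac7 flipped to -0.0204. In the other direction, Itgav, the integrin alpha V subunit, read 3.93 ± 0.168 against 2.99 ± 0.0951 FPKM, and Iqgap2, a cytoskeletal scaffold, 9.73 ± 1.37 against 6.54 ± 0.495 FPKM. Slfn2, Trpm3, Hspa4l, Wwp1, Zfp804a, Zfp708, Vmp1 and Eif5a2 had log2 differences from -0.51 to -0.22, below every control in all 4 knockdown libraries. With summed transcripts the difference for Trpm3 was -0.04 and for Ccdc74a 0.20, and with the GC content and length trend removed it was 0.29 for Vps37d, 0.23 for Lrrc73, 0.21 for Ccdc74a and -0.14 for Wwp1. The limma adjusted p of all 20 was 0.266.

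Of the 31 gene lists, 4 passed the threshold with camera at the preset correlation, and 0 passed with an estimated correlation or with fry. No list held a member past the threshold over all genes. At the preset correlation, 7, 8 and 7 lists passed without control replicates 1, 3 and 4, and 7 without knockdown replicate 4. The largest difference was in markers of striatal projection neurons, the dopamine-responsive cells of the neighbouring striatum, whose 29 measured members were all lower in the knockdown group (mean relative log2 difference -0.68, camera adjusted p = 2.95e-08 at the preset correlation; adjusted p = 0.92 with an estimated correlation). Pde10a, the phosphodiesterase of these cells, read 32.4 ± 14.8 against 9.65 ± 5.24 FPKM, although the sum of its listed transcripts went the other way (log2 difference 1.20). The dopamine receptors Drd1 and Drd2 read 25.1 ± 11.8 against 13.5 ± 8.83 FPKM and 18.8 ± 10.3 against 8.89 ± 6.58 FPKM (SD, n = 4 each; limma adjusted p 0.451 and 0.47). By library, the striatal score was 0.86, 0.34, 0.71 and -0.58 in controls and -0.63, 0.0025, 0.25 and -0.94 in the knockdown group, so the groups overlapped (exact permutation p = 0.143).

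Cytosolic ribosomal protein genes were higher, by 0.11 on the log2 scale relative to all genes, in 80 of 82 members (camera adjusted p = 2.57e-12 at the preset correlation; adjusted p = 0.92 with an estimated correlation). Rps19 read 15.9 ± 0.996 against 19.6 ± 1.96 FPKM and Rpl41 104 ± 2.12 against 119 ± 8.10 FPKM. In this list 32 members were at an unadjusted limma p under 0.05 and 0 passed when adjusted over the list alone. Removing the GC content and length trend left a difference of 0.06. Myelin and oligodendrocyte genes were lower by -0.21 in 28 of 30 members (camera adjusted p = 0.00134; adjusted p = 0.92 with an estimated correlation), and the call ended without knockdown replicate 1 (-0.11) or knockdown replicate 4 (-0.08), whose myelin scores were -0.41 and -0.46. Those 2 libraries also had the lowest striatal scores. Control replicate 4, however, had a striatal score of -0.58, near the -0.63 of knockdown replicate 1, and a myelin score of 0.06. With the striatal score as a covariate the myelin difference turned to 0.0185 (camera adjusted p = 0.83). The striatal score was itself lower on average in the knockdown group, so this covariate can also remove part of a group difference. Without knockdown replicate 3 the myelin difference was -0.34. Il33, an alarmin cytokine made by oligodendrocytes, read 26.1 ± 3.47 against 17.2 ± 7.36 FPKM, and Apod 42.1 ± 8.44 against 33.6 ± 7.38 FPKM. Voltage-gated ion channel genes were lower by -0.11 in 35 of 50 members (camera adjusted p = 0.0314; adjusted p = 0.92 with an estimated correlation), with Cacnb4 at 39.1 ± 1.12 against 33.0 ± 3.73 FPKM and Kcnc4 at 15.4 ± 2.66 against 19.8 ± 1.04 FPKM. That call ended under median-of-ratios rescaling (adjusted p = 0.0595) and quantile normalization (adjusted p = 0.0702), with summed transcripts (adjusted p = 0.0501), and without control replicate 2 (adjusted p = 0.14) or knockdown replicate 3 (adjusted p = 0.254). The difference in these alternatives ran from -0.108 to -0.0894.

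**Figure D3:**
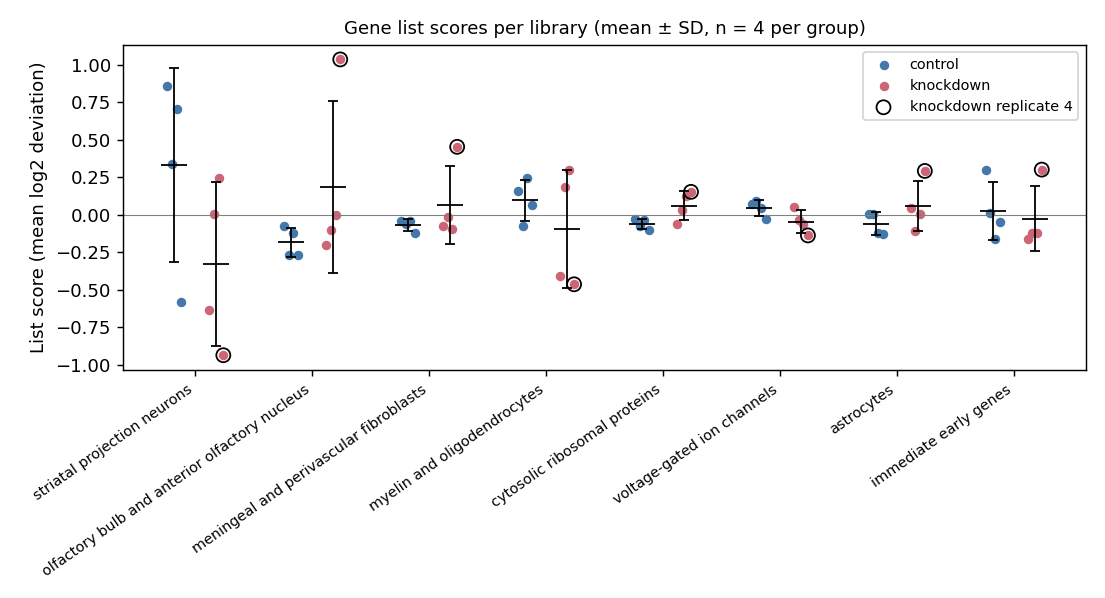
List score (y axis, mean log2 deviation of the members from their means over the 8 libraries) for 8 gene lists (x axis), with 1 point per library, blue for control and red for knockdown, black bars for the mean ± SD of 4 libraries and a ring around knockdown replicate 4. That library lay at 1.04 for olfactory and -0.94 for striatal markers.

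Synaptic lists did not pass the camera test in the comparison as planned. The Homer and mGluR scaffold list had a relative difference of -0.04 over 22 members (adjusted p = 0.479), glutamate receptors and postsynaptic density genes -0.02 over 47 (0.537), presynaptic release genes -0.04 over 44 (0.692) and neuromodulator receptors -0.13 over 36 (0.0892; 0.0208 without control replicate 1). Neuromodulator receptors had an adjusted p = 0.92 with an estimated correlation on all 8 libraries. With 1 library left out, the scaffold difference ran from -0.07 to -0.02. The presynaptic difference was -0.015 without knockdown replicate 4, whose score was -0.09, and -0.03 without control replicate 4. In the list of glutamate receptors and postsynaptic density genes, Neto1, an auxiliary subunit of kainate and NMDA receptors, read 29.9 ± 1.80 against 21.4 ± 3.45 FPKM and Grik5 36.0 ± 1.51 against 42.0 ± 2.63 FPKM (SD, n = 4, control against knockdown). The presynaptic genes Doc2a and Syt7 read 13.1 ± 2.10 against 17.7 ± 1.17 FPKM and 47.0 ± 3.04 against 55.3 ± 3.26 FPKM, and Agap2, of the scaffold list, 136 ± 7.49 against 154 ± 7.47 FPKM. Among neuromodulator receptors, the serotonin receptor Htr2a read 11.7 ± 0.766 against 8.85 ± 1.46 FPKM and the nicotinic receptor Chrna7 2.34 ± 0.160 against 1.65 ± 0.345 FPKM. None of these 7 passed when adjusted over the list alone. Over the alternatives, log2 differences ran from 0.07 to 0.21 for Agap2, 0.10 to 0.26 for Grik5, 0.26 to 0.51 for Doc2a and 0.15 to 0.26 for Syt7. They ran from -0.54 to -0.34 for Neto1, -0.50 to -0.30 for Htr2a and -0.50 to -0.26 for Chrna7.

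The list of HuD (ELAVL) family and neuronal RNA-binding proteins did not move as a set (relative difference -0.0067, mean 0.0087 and median -0.0087, camera adjusted p = 0.605), but 3 of its 37 members passed when adjusted over the list alone, and 0 over all genes. Celf5 (38.8 ± 1.84 against 44.8 ± 1.54 FPKM) and Celf4 (55.6 ± 2.31 against 65.1 ± 4.30 FPKM) were higher in all 4 knockdown libraries than in any control, and the splicing regulator Rbfox1 (113 ± 5.54 against 90.8 ± 9.26 FPKM) was lower in all 4 (SD, n = 4; limma with Benjamini-Hochberg adjustment over the list, adjusted p = 0.0482 for each). In the list of oligodendrocyte precursors (0.02 over 20 members, camera adjusted p = 0.605), Cspg5, a chondroitin sulfate proteoglycan, passed over the list alone (22.5 ± 0.450 against 27.4 ± 2.24 FPKM, limma adjusted p = 0.0315). The blood cell list had a relative difference of -0.05 over 8 members (camera adjusted p = 0.897), and -0.31 with the striatal score as a covariate (adjusted p = 0.0179). With an estimated correlation its adjusted p = 0.949.

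Activity and stress genes did not pass in the comparison as planned. Immediate early genes differed by -0.06 over 44 members (camera adjusted p = 0.194), with Nr4a2 at 12.7 ± 5.02 against 6.69 ± 2.16 FPKM, Arc at 55.7 ± 24.6 against 37.5 ± 16.8 FPKM and Fos at 8.17 ± 3.28 against 7.60 ± 3.14 FPKM (SD, n = 4 each). Of the 44 members, 18 were higher in the knockdown group and 26 lower. Heat shock and stress genes differed by -0.07 over 31 members (0.0718), glucocorticoid response genes by -0.09 over 24 (0.0718), circadian clock genes by -0.05 over 17 (0.238), apoptosis and DNA damage genes by 0.06 over 21 (0.291), and interferon response genes by -0.05 over 31 (0.291). Sgk1, a glucocorticoid-induced kinase, read 27.8 ± 4.05 against 18.8 ± 6.78 FPKM and Klf9 68.9 ± 1.34 against 56.7 ± 7.33 FPKM. Without knockdown replicate 4, immediate early genes (-0.17, camera adjusted p = 0.00015), heat shock genes (-0.18, adjusted p = 1.08e-06) and glucocorticoid response genes (-0.09, adjusted p = 0.0405) passed at the preset correlation. Without control replicate 3, the same 3 lists (-0.13, -0.14 and -0.12) and interferon response genes (-0.10) passed. Glucocorticoid response genes also passed without knockdown replicate 3 (-0.14) and circadian clock genes without control replicate 4 (-0.09). Other omissions made these differences smaller or turned them. Heat shock genes differed by -0.0169, -0.03 and -0.03 without control replicate 2, knockdown replicate 2 and knockdown replicate 3, and immediate early genes by 0.0234 without control replicate 1 and by -0.03 without knockdown replicate 1, 2 or 3. Without control replicate 1 the interferon difference was 0.0169, and without knockdown replicate 1 the glucocorticoid difference was -0.05. Circadian clock genes differed by -0.0093, -0.03 and -0.02 without control replicates 1 and 2 and knockdown replicate 3. Apoptosis and DNA damage genes differed by 0.02 without knockdown replicate 4, whose score was 0.18, by 0.09 without knockdown replicate 2, and by 0.0084 with the striatal score as a covariate. With all 8 libraries, immediate early, heat shock and glucocorticoid response genes passed with array weights (camera adjusted p = 0.043, 0.000913 and 0.0279) and with the GC content and length trend removed (0.0483, 0.00984 and 0.0294). The striatal score as a covariate gave calls for immediate early (camera adjusted p = 0.0422) and heat shock genes (adjusted p = 5.8e-05). None of these lists passed with an estimated correlation on all 8 libraries (adjusted p = 0.92 for each). Cholesterol synthesis genes differed by 0.05 over 25 members (camera adjusted p = 0.257), nuclear-encoded respiratory chain genes by 0.03 over 80 (0.0892) and mitochondrially encoded genes by 0.0066 over 13 (0.847). Cholesterol synthesis genes passed without control replicate 4 or knockdown replicate 4 (0.08 in both) and with array weights (0.08, camera adjusted p = 0.021), and respiratory chain genes without control replicate 4 (0.04), knockdown replicate 1 (0.04) or knockdown replicate 3 (0.05). Cholesterol synthesis genes differed by 0.02 without knockdown replicate 2 and by 0.03 without control replicate 1, control replicate 2 or knockdown replicate 1. Respiratory chain genes differed by 0.0063 without knockdown replicate 4 and by 0.02 without control replicate 1, and turned to -0.0126 with the GC content and length trend removed and to -0.0091 with the striatal score as a covariate. With an estimated correlation on all 8 libraries both had an adjusted p = 0.92.

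Cell type and region markers other than those above did not pass in the comparison as planned. Astrocyte genes differed by 0.10 over 28 members (camera adjusted p = 0.0598), with the gap junction gene Gja1 at 9.74 ± 2.85 against 15.0 ± 2.06 FPKM and Hes5 at 5.79 ± 1.33 against 8.23 ± 0.940 FPKM (SD, n = 4). This list passed without control replicates 1 and 2 and knockdown replicates 2 and 3, each left out alone (camera adjusted p = 0.0139, 0.00675, 0.00055 and 0.0407), and on all 8 libraries with the GC content and length trend removed (0.11, adjusted p = 0.00984) or with summed transcripts (0.12, adjusted p = 0.0198). With an estimated correlation on all 8 libraries it did not pass (adjusted p = 0.92). Without knockdown replicate 4, whose scores were 0.29 on the astrocyte and 0.24 on the GABA interneuron list, the differences were 0.03 for astrocyte, 0.0023 for reactive astrocyte and 0.04 for GABA interneuron genes. Reactive astrocyte genes differed by 0.05 over 19 members (0.454), microglia genes by 0.0013 over 29 (0.769), disease-associated microglia and macrophage genes by -0.0018 over 14 (0.823; mean 0.0136 and median 0.0178 before subtracting all genes), endothelial and mural genes by 0.02 over 35 (0.823) and GABA interneuron genes by 0.10 over 34 (0.454). Cortical layer markers differed by -0.05 over 42 members (0.257), thalamus and basal forebrain markers by 0.08 over 15 (0.823), and choroid plexus and ependyma markers by 0.07 over 6 (0.823; camera's direction was down). Thalamus and basal forebrain markers turned to -0.0224 without control replicate 4, and their largest difference in any alternative was 0.32. Choroid plexus and ependyma markers ran from 0.03 to 0.16 over the alternatives. Olfactory bulb and anterior olfactory nucleus markers differed by 0.35 over 14 members (0.0995) and meningeal and perivascular fibroblast markers by 0.12 over 16 (0.145). Knockdown replicate 4 had scores of 1.04 and 0.45 on these lists, and without it the differences were 0.07 and 0.0027. The olfactory list passed at the preset correlation without control replicate 1, knockdown replicate 1 or knockdown replicate 2 (adjusted p = 0.041, 0.0239 and 0.0369), and the meningeal list without knockdown replicate 1 (adjusted p = 0.0481). With an estimated correlation on all 8 libraries both had an adjusted p = 0.92.

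In the transcript table, 6 of 23415 transcripts passed the threshold (limma, Benjamini-Hochberg adjusted), 3 higher and 3 lower, all from Kmt2d, Klc1 and Cacna1b. In Kmt2d, a histone H3 lysine methyltransferase, Kmt2d-202 fell by 3.10 on the log2 scale, from 7.61 ± 0.452 to 0.0019 ± 0.0015 FPKM (SD, n = 4 each; adjusted p = 1.23e-05), while Kmt2d-201 rose from 0.573 ± 0.274 to 8.73 ± 0.374 FPKM (adjusted p = 0.000384). In Klc1, a kinesin light chain of axonal transport, Klc1-203 fell from 157 ± 10.1 to 67.9 ± 4.64 FPKM (limma adjusted p = 0.000699), and Klc1-201 (31.4 ± 3.35 to 63.1 ± 6.10 FPKM, adjusted p = 0.0358) and Klc1-204 (13.7 ± 0.254 to 22.1 ± 1.499 FPKM, adjusted p = 0.0211) rose. Cacna1b-204, an isoform of the presynaptic N-type calcium channel, was listed at 6.65, 5.67, 5.06 and 5.17 FPKM in the controls and at 0 in all 4 knockdown libraries (limma adjusted p = 7.86e-05). Cacna1b-201, Cacna1b-202 and Cacna1b-205 were higher without passing (log2 differences 0.70, 0.97 and 0.58, limma adjusted p = 0.565 for each). No other listed Cacna1b isoform had a lower mean in the knockdown group. Kmt2d-201 and Kmt2d-202 span nearly the same positions (chromosome 15, 98831672 to 98871204 and 98831669 to 98871183). The log2 differences of the summed isoforms were 0.05 for Kmt2d, -0.07 for Klc1 and 0.15 for Cacna1b. At an unadjusted p under 0.05 there were 1863 transcripts, 7.96% of those tested. With 1 library left out, 9 to 19 transcripts passed, more than 1.5 times the count with all libraries for each library except control replicate 3 (9). Of the 6 named transcripts, 4 still passed without control replicate 1, 2 or 3 and 5 without knockdown replicate 1, 2 or 3. Klc1-201 was lost in all of these (limma adjusted p from 0.0511 to 0.114) and Klc1-204 without control replicate 1, 2 or 3 (limma adjusted p = 0.0526, 0.0525 and 0.0696). Both were also lost without the trend and robust settings (limma adjusted p = 0.0617 for each) and with the replicate block (limma adjusted p = 0.666 and 0.523). Klc1-201 was lost with the striatal score as a covariate as well (limma adjusted p = 0.343). Over the 17 alternatives the log2 difference ran from 0.925 to 1.048 for Klc1-201 and from 0.61 to 0.70 for Klc1-204.

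**Figure D4:**
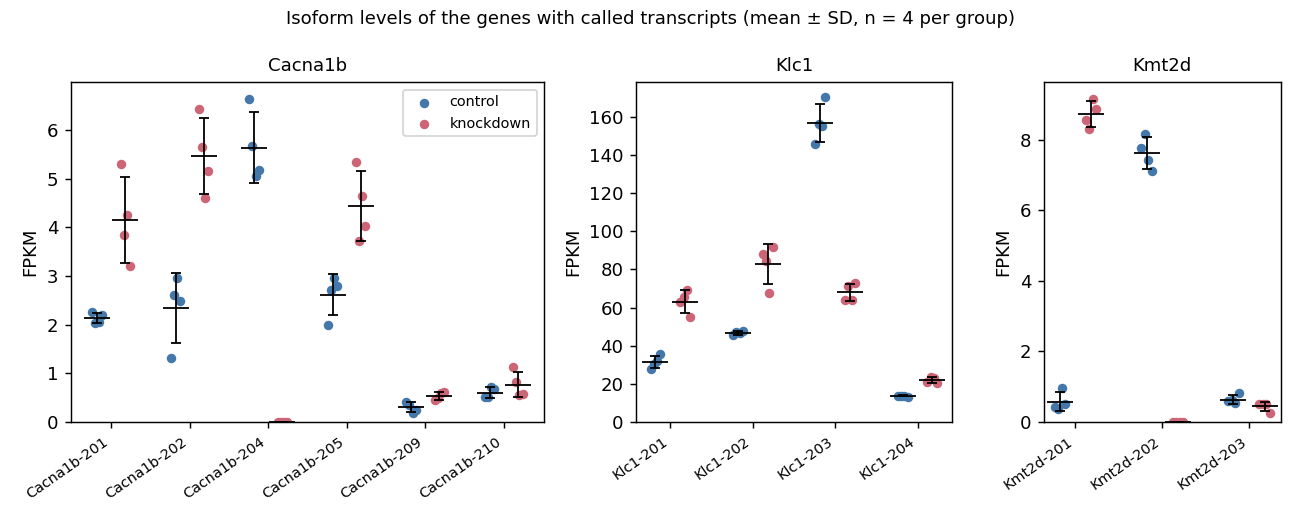
FPKM (y axes) of each listed isoform (x axes) of Cacna1b, Klc1 and Kmt2d, with 1 point per library, blue for control and red for knockdown, and black bars for the mean ± SD of 4 libraries. Isoforms of the same gene lie on opposite sides, with Kmt2d-202 near 0 and Kmt2d-201 at 8.73 FPKM in the knockdown group.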

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

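The tests of other splits for the gene and transcript counts, and those of the striatal markers, were chosen or had their outcome seen before their bounds were written; the remaining tests had bounds written first. A library far from the other 3 of its group was found in 14 of 250 groups examined (5.60%), where chance gives about 1 in 20.

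Knockdown replicate 4 held 6 of these: Calb2 at 33.6 FPKM against 4.17 to 5.24 in the others, mt-Co3 at 2524 FPKM against 2031 to 2114, and list scores of 1.04 for olfactory, 0.45 for meningeal, 0.30 for immediate early and 0.30 for heat shock genes. It also lay alone on the first principal component (29.2 against -11.4 to 7.03, 34.2% of the variance). Among Homer1 isoforms, Homer1-202 read 10.3 FPKM in knockdown replicate 3 against 12.2 to 12.4 in the others, and Homer1-207 read 6.31 FPKM in knockdown replicate 1 against 1.04 to 1.57, and 1.36 FPKM in control replicate 3 against 1.81 to 1.86. Hopx read 15.3 FPKM in control replicate 4 against 13 to 13.1, and Dennd6b 15.1 FPKM in control replicate 1 against 16.2 to 16.4. Trpm3 read 1.91 FPKM in control replicate 1 against 1.70 to 1.72, Sgk1 33.8 FPKM in control replicate 1 against 25.4 to 26.0, and Deptor 4.55 FPKM in knockdown replicate 3 against 5.41 to 5.53.

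Striatal markers were lower in the knockdown group. If the libraries held unequal amounts of striatal tissue, the markers should vary together inside each group, and they did. The estimated inter-gene correlation of the list was 0.799, against a median of 0.259 over the 31 lists. Other lists were also high, with 0.793 for myelin, 0.711 for mitochondrially encoded and 0.661 for cytosolic ribosomal genes. Markers of 1 cell type can vary together whatever sets their level, so the correlation cannot tell unequal tissue from another cause. Control replicate 4 (-0.58) lay near knockdown replicate 1 (-0.63). Unequal dissection remains a candidate explanation, as does an effect of the knockdown. The exact permutation test of the scores did not pass (p = 0.143). Of the 4 knockdown libraries, 2 lay inside the control range and the others (-0.63 and -0.94) below it, so an effect of the knockdown is neither shown nor excluded.

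More genes than expected had an unadjusted p under 0.05, and 1 of the 35 distinct splits of the 8 libraries, the real one, gave as many (1842, highest other 1675). The real split thus ranked first, which is the smallest share the splits can give. Its bound was not written beforehand, so chance is not excluded. Knockdown replicate 4 as the only source was bounded beforehand at 1.5 times the expected count, and without it 1420 genes remained against 649 expected. That bound proved wrong as a test, since 4 of 35 splits of the 7 remaining libraries gave as many (highest other 1830). The same held for a GC content or length trend: removing it left 1185 genes against 646 expected, and 5 of 35 splits then gave as many (highest other 1557). With the striatal score as a covariate the count was 1046, and other splits were not run with that covariate. Whether the excess comes from the trend, from that library, from unequal striatal tissue or from the knockdown cannot be told apart. Removing the trend or that library leaves a count that other splits reach.

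Opposite isoforms of a gene were called between the groups in Kmt2d and Klc1. If the division of reads between isoforms was unstable, libraries of 1 group should show similar jumps, and inside the control group alone 177 transcripts went from under 0.05 FPKM in 1 library to above 5 in another while the host's summed value stayed within 1.5-fold (196 inside the knockdown group). Of the 35 splits, 15 called as many transcripts as the real 6 (highest other 16), and 6 called as many genes in opposite directions as the real 2 (highest other 3). Chance is not excluded for these calls. The jumps were counted over all transcripts, and none of the called isoforms made such a jump inside a group. Klc1-203, for example, read 146 to 170 FPKM in the controls and 63.8 to 72.7 FPKM in the knockdown libraries. A small p selects isoforms that are steady inside groups, so unstable division of reads is neither shown nor excluded for these calls. An effect of the knockdown on splicing stays open. The bound written beforehand for it (5% of the splits) bears on chance and cannot exclude an effect.

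The count of genes past the threshold was 0 (highest other split 4), so that all 35 splits give as many by construction and nothing about chance follows. For the count of gene lists at the preset correlation (4, highest other split 17), 35 of 35 splits gave as many, so chance is not excluded. Splits that call several times the real number of lists go with a structure of the samples that list members share. The preset correlation of 0.01 lies below the median estimate of 0.259, and with estimated correlations the real split called 0 lists. The other splits were run at the preset correlation alone.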

How the results depend on the processing

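Alternatives using GC content and length, summed transcripts or the striatal score, and all those for the count at an unadjusted p, were chosen after seeing the data. No counts or TPM were given, so the planned change of tool or unit was not run. The direction of Homer1 held in its 19 alternatives and that of Homer1-204 in 17, as removal of the GC and length trend and summed transcripts were not run on isoforms (log2 differences from -0.39 to -0.23 and from -0.73 to -0.49; limma adjusted p from 0.239 to 0.614 and from 0.461 to 0.898), and 0 Homer1 isoforms passed in any of the 17.

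No gene was called except with 1 library left out, from 0 to 2 genes: Ppm1a (-0.99) without control replicate 1, Pcdhgc3 (2.43) without control replicate 2, Uhrf1bp1l (-0.90) without knockdown replicate 3, and Atp6ap1 (-0.70) and Bcl2l2 (1.63) without knockdown replicate 4. These were named after their values were seen. Leaving out 1 library gave 9 to 19 transcripts, 4 to 8 gene lists and 1199 to 2174 genes at an unadjusted p under 0.05. That last count was 1185 without the GC and length trend and 1046 with the striatal score as a covariate. Lists called numbered 8 with array weights, 8 without the GC and length trend, and 0 with an estimated correlation or fry. The labels do not say whether same-numbered libraries were paired, and no pairing was detected. Deviations of same-numbered libraries correlated at -0.185, -0.0723, 0.20 and -0.0174, and 2 of the 8 libraries correlated best with their own number. These values cannot exclude pairing. The fit with the replicate block called 0 genes, 4 transcripts and 4 lists.

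The following directions turned; the cause was not tested. With 1 library left out, log2 differences ran from -0.34 to 0.27 for Homer1-203, -0.0626 to 0.53 for Homer1-205, -0.27 to 0.35 for Homer1-207 and -0.00603 to 0.14 for Homer3. Relative list differences then ran from -0.0165 to 0.00615 for neuronal RNA-binding proteins, -0.17 to 0.0848 for blood, -0.0420 to 0.0448 for disease-associated microglia, -0.0228 to 0.0447 for endothelial, -0.17 to 0.0234 for immediate early, -0.0980 to 0.0169 for interferon, -0.0426 to 0.0495 for microglia, -0.0381 to 0.0352 for mitochondrially encoded, -0.0197 to 0.0552 for oligodendrocyte precursor and -0.0224 to 0.11 for thalamus genes. With summed transcripts, Hdac7 was -0.0204, Mvk -0.0219, Pde10a 1.20 and disease-associated microglia 0.0239. Without the GC and length trend, Homer3 was -0.0417, RNA-binding proteins 0.0283, microglia -0.0216 and respiratory chain genes -0.0126. With the striatal score, Homer1-203 was 0.10, RNA-binding proteins 0.00316, disease-associated microglia 0.0132, myelin 0.0185 and respiratory chain genes -0.00913. Array weights gave -0.00923 for endothelial, -0.0394 for microglia and -0.0322 for mitochondrially encoded genes; quantile normalization gave -0.000675 for microglia and -0.00517 for mitochondrially encoded genes. For disease-associated microglia, a pseudocount of 0.1 gave 0.00985 and a mean of at least 2 gave 0.0049. Read depth is unknown, so what it limits cannot be stated.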

Other observations

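Markers of olfactory tissue differed widely inside the knockdown group. Cdhr1 and Doc2g, genes of olfactory bulb output neurons, read 0.607 ± 0.1797 and 0.835 ± 0.159 FPKM in controls and 3.07 ± 4.58 and 3.26 ± 4.76 FPKM in the knockdown group (SD, n = 4 each), with knockdown replicate 4 at 9.93 FPKM for Cdhr1. The vesicular glutamate transporter Slc17a7, carried by cortical excitatory neurons, read 128 ± 20.9 against 137 ± 10.4 FPKM, and Gad1, which makes GABA, 46.6 ± 2.70 against 43.6 ± 6.49 FPKM.

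The immediate early gene score was 0.30, 0.0089, -0.16 and -0.05 in control replicates 1 to 4 and -0.16, -0.12, -0.12 and 0.30 in knockdown replicates 1 to 4. Homer1-204, the activity-induced short form, read 25.7, 24.8, 17.3 and 21.1 FPKM in the same controls and 12.9, 17.2, 10.3 and 16.4 FPKM in the same knockdown libraries. No relation between the score and Homer1-204 was tested.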
